A study of Mus musculus with 6 samples.

How the data were processed

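PolyA RNA was sequenced in paired-end mode from unstimulated CH12F3-G cells, 3 WT and 3 Dot1l knockout libraries, with Drosophila Kc167 cells mixed in before extraction as a spike-in, per the labels' protocols. The submitters' processing notes name fastp 0.23.1, STAR 2.7.9a, featureCounts, DESeq2 1.38.2, SAMtools 1.16.1 and deepTools 3.5.0 with the builds mm10 and dm6, without the role or order of each. Whether counting used strand is not given in the sources used here, so overlapping genes on opposite strands cannot be told apart.

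The table used here holds 55244 mouse genes and no fly rows, so the share of spike-in reads and a scaling to them were not analysed here. Its 6 library columns are signal in the form of counts that the authors divided by 1 size factor per library, per the file headers and the series' design text. All of the values above 0 (100%, tolerance 0.01 reads) were whole multiples of the smallest value in their library, which gave whole reads back, between 42548572 and 53910667 per library. Median-of-ratios factors of the same genes differed from the authors' factors. Divided by the latter, they gave 0.921, 1.18 and 0.937 in WT and 0.998, 0.988 and 1.05 in knockout replicates 1 to 3. The deposited table also gives the authors' log2 fold changes, a score (the standard error and the test statistic) and p-values, raw and adjusted, per the file headers. Its log2 fold changes were matched to within 1.2e-09 by DESeq2 on the recovered reads with the deposited factors and a term separating replicate 3 from replicates 1 and 2, while without that term 6607 genes differed by more than 0.1.

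Gene positions came from GENCODE release M21 (GRCm38, the same assembly as mm10) by identifier, which matched 55063 genes. The main test was limma 3.58.1 in R 4.3.3 (trend and robust, two-sided) on log2(normalized count + 1) of the 15794 genes with a mean of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 31 gene lists (711 entries, 708 matched to 1 gene) were fixed before the data were examined, as were the tests and most alternatives. The 30 lists with at least 5 tested members entered camera with a preset correlation of 0.01, adjusted over the lists. Lists were not chosen on these samples. A few genes that the naming rule picked are not reported. The rule, fixed in advance, took Dot1l and Ighm, then the 12 highest and 12 lowest fold changes among called genes with a mean of at least 100 and no overlap between groups, leaving out predicted genes and antibody V, D and J segments. From each list it took up to 2 rising and 2 falling members of lowest adjusted p, or the 2 best expressed where none passed, and the best expressed member of each list of another cell type. Aff1, Mllt6, Prdm1, Irf4, Xbp1, Pax5 and all further called list members were named after their values were seen, as were genes given in the closing section outside the rule.

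Same-numbered libraries deviated together from their group means, with correlations of 0.338, 0.314 and 0.509. WT replicate 1 also correlated at 0.363 with knockout replicate 2, and WT replicate 2 at 0.2485 with knockout replicate 1. A replicate 3 that stands apart in both genotypes gives such values by itself, since deviations from a group mean cancel out. They therefore do not show that replicates 1 and 2 are paired by number. The labels do not say what a number stands for. The fit with the replicate number as a block has 2 residual degrees of freedom, and limma estimated an infinite prior for it. Its p-values therefore treat the spread as known and are smaller than 3 pairs can justify. The fit of replicates 1 and 2 alone also had 2 residual degrees of freedom and an infinite prior, so its p-values are too small likewise. Replicates 1 and 2 differed by a mean chi-square per gene of 3.30 in WT and 4.20 in knockout, above the 1 that sampling noise gives, and were kept as separate libraries.

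The alternatives were other pseudocounts, filters and scalings, each library left out in turn (over the same tested genes), the replicate block, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads, camera with an estimated correlation, and fry. A term for replicate 3, replicates 1 and 2 alone, and replicates 1 and 2 averaged were added after the data were seen. On counts simulated for the same 15794 genes with the dispersions of these data, limma called 4.48% of 67 genes changed 1.5-fold, 46.3% of 67 changed 2-fold and 83.3% of 66 changed 4-fold, all in the right direction, and 1 of 15554 unchanged genes. Camera found both planted lists of 20 genes changed 1.5-fold in their direction. The simulated genes and libraries varied independently, without correlation between genes, near-alike replicates 1 and 2 or a shared shift of replicate 3. The simulation therefore cannot show how often limma or camera with the preset correlation made false calls in these data. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.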

Results

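Transcript levels were measured in CH12F3-G cells, a mouse B lymphoma line subcloned from CH12F3 and used to study antibody class switching, without stimulation. WT cells were compared with cells whose Dot1l gene had been disrupted by CRISPR, with 3 libraries in each group. Whether the knockout libraries came from a single clone or several is not given in the sources used here. Differences between clones therefore cannot be told apart from the loss of Dot1l in any result below. Dot1l encodes the methyltransferase that modifies histone H3 in the body of transcribed genes, and the series title places the comparison among questions of polymerase elongation, pausing and antibody gene mutation. Each library held between 42548572 and 53910667 whole reads over 55244 mouse genes. Values are normalized counts, given as mean ± SD with n = 3 per group, and fold changes are on the log2(normalized count + 1) scale, which understates the change of weakly expressed genes. The labels number the replicates but nothing says that they were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

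Dot1l itself (chromosome 10, 80755206 to 80795461, GRCm38) was lower in every knockout library than in every WT library. Its level was 4169 ± 942 in WT and 1689 ± 98.7 in knockout, a log2 fold change of -1.28 (SE 0.20, limma adjusted p = 9.1e-04). The knockout libraries held 1615, 1650 and 1801 normalized counts, and the WT libraries 3899, 5217 and 3391. The values are per gene, so they do not show which exon was lost. With replicates 1 and 2 averaged into 1 library per genotype, an alternative chosen after the data were seen, the log2 fold change was -1.20 and the adjusted p 0.0888.

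Genotype separated the libraries along the first principal component, which carried 53.5% of the variance. The second, with 28.9%, separated the replicate 3 libraries from replicates 1 and 2 of both genotypes. Replicates 1 and 2 differed from each other by a biological coefficient of variation of 2.60% in WT and 3.11% in knockout, beyond sampling noise, against 14.5% between WT replicates 1 and 3 and 31.9% between knockout replicates 1 and 3. Mitochondrial transcripts took 4.81% and 4.68% of the reads in WT and knockout replicate 3, against 3.49% to 4.12% in the other libraries.

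**Figure D1:**
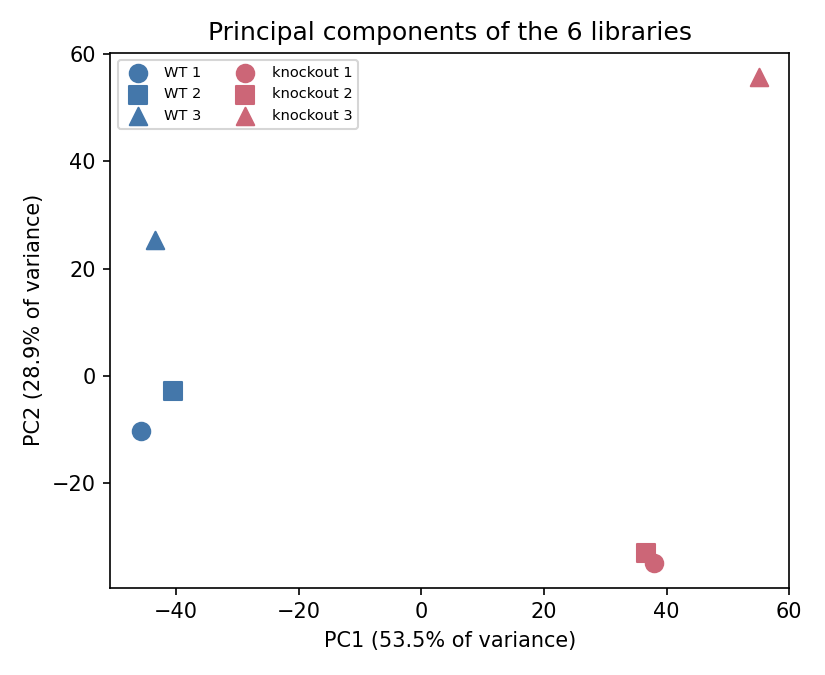
Principal components of the log2 values of the tested genes, with PC1 on the x axis and PC2 on the y axis (percent of variance in the axis labels), 1 point per library, coloured by genotype and shaped by replicate number. WT libraries lie at -45.7 to -40.5 on PC1 and knockout libraries at 36.7 to 55.0, while the replicate 3 libraries lie highest on PC2, at 25.4 and 55.7.

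The strongest increases in knockout included Arhgap18, Ifitm1 and Vim, and the strongest decreases included the antibody joining chain. Arhgap18, a GTPase-activating protein, was at 0.625 ± 1.08 normalized counts in WT and 355 ± 273 in knockout. Ifitm1, an interferon-inducible membrane protein (chromosome 7, 140967221 to 140969825), rose 45.8-fold, from 134 ± 29.1 to 6146 ± 991 (adjusted p = 7.0e-09). Vim, the intermediate filament protein vimentin (chromosome 2, 13573927 to 13582826), rose 30.5-fold, from 180 ± 47.1 to 5655 ± 2158 (adjusted p = 7.0e-07). Jchain, which joins IgM and IgA into polymers (chromosome 5, 88519809 to 88527891), fell 13.7-fold, from 35864 ± 5277 to 2639 ± 524 (adjusted p = 6.4e-08).

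Other genes of large increase were Rasgef1b (92.2-fold), Plet1 (53.02-fold), Impg1 (41.5-fold), the tight junction protein gene Tjp3 (37.5-fold), the cytokine gene Csf2 (34.7-fold), the decoy receptor gene Il1r2 (26.1-fold), Ppp2r2b (24.5-fold) and the receptor tyrosine kinase gene Axl (23.2-fold). The other genes of largest decrease were Ms4a4c (21.4-fold), the kinase gene Plk2 (12.7-fold), the troponin gene Tnnt3 (10.4-fold), Mfsd10 (9.66-fold), the lambda light chain constant gene Iglc1 (6.22-fold), Gvin1 (5.75-fold), Wnt16 (5.71-fold), Cox6a2 (5.66-fold), Pdzd2 (4.89-fold), Yes1 (4.75-fold) and Fgf21 (4.70-fold). All 3 knockout values lay on one side of all 3 WT values for each of these genes, as the rule for naming them required. Gvin1 and Iglc1 have close copies, so their counts are uncertain. Without WT replicate 2 the adjusted p rose to 0.0677 for Plk2, 0.0701 for Iglc1, 0.124 for Cox6a2 and 0.0823 for Fgf21, and without WT replicate 3 to 0.0633 for Iglc1 and 0.0607 for Cox6a2.

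**Figure D2:**
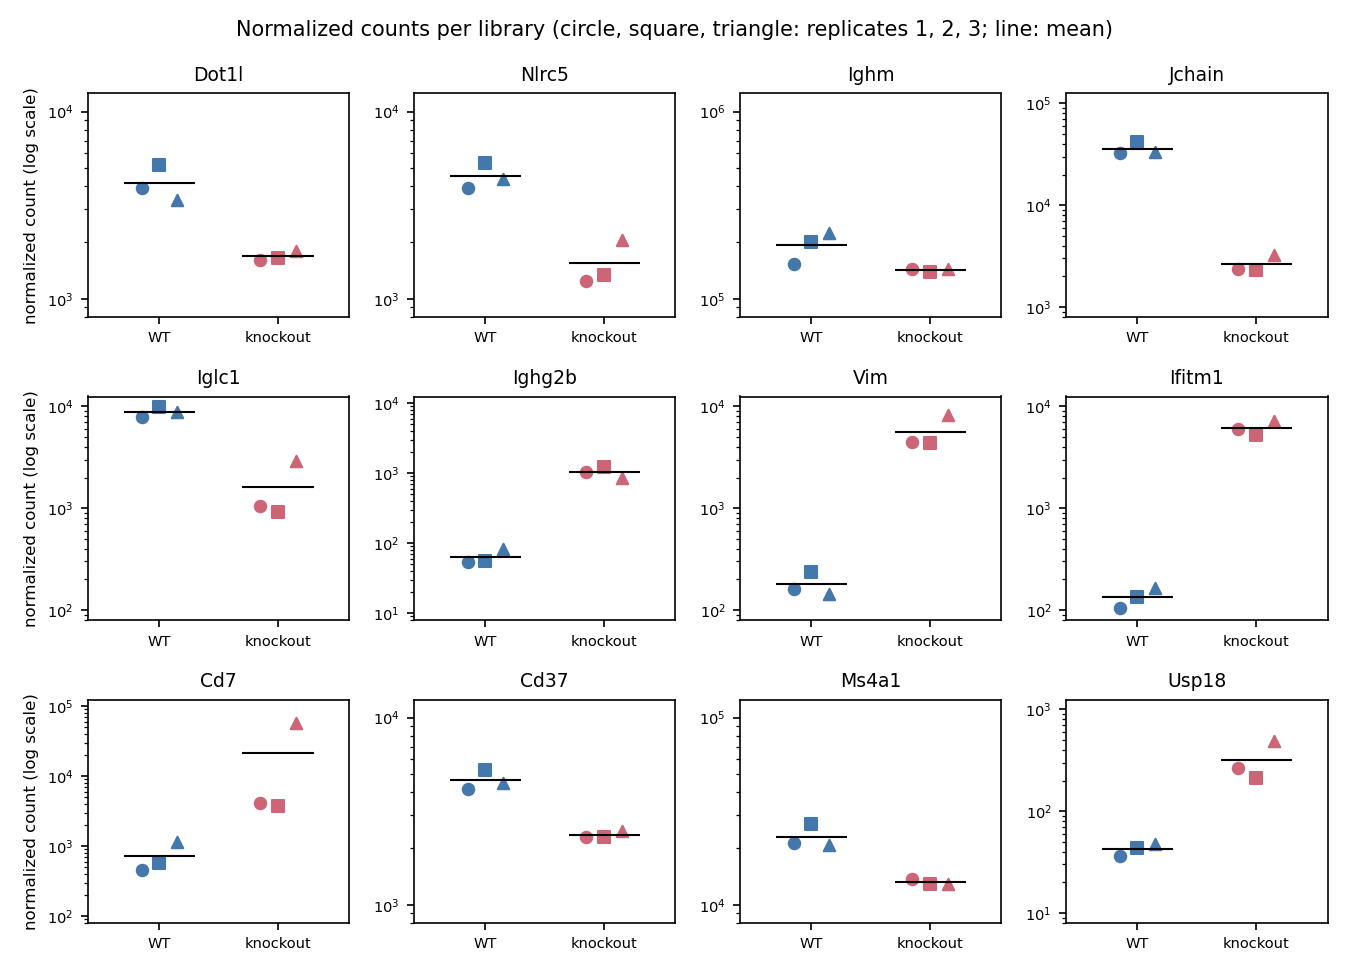
Normalized counts (log y axis) of 12 genes in the 6 libraries, WT in blue and knockout in red, with circle, square and triangle for replicates 1, 2 and 3 and a line at the group mean. Dot1l, Nlrc5, Ighm, Jchain, Iglc1, Cd37 and Ms4a1 lie lower in all 3 knockout libraries, and Ighg2b, Vim, Ifitm1, Cd7 and Usp18 higher. Ighm and Cd7 did not pass in limma, and Cd7 (57235) is highest in knockout replicate 3.

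Across 15794 genes with a mean of at least 10 normalized counts, 741 rose and 308 fell in knockout (limma, adjusted p under 0.05), and 653 of the former and 186 of the latter changed at least 2-fold. With the replicate number as a block, 1270 rose and 719 fell, and all 1049 genes called without the block were among them. The groups did not overlap for 3409 genes (21.6%, against 10% by chance if the 6 libraries are independent), including all 1049 called genes. Since replicates 1 and 2 are nearly alike, the share by chance may be higher, and 21.6% need not exceed it. The median log2 fold change of all genes was -0.0067, and the mean of the library medians was 0.0086 higher in knockout (exact two-sided permutation p = 1; 3 libraries against 3 cannot give less than 0.1). The WT library medians spread widely, at -0.1334, 0.2314 and -0.0907 (log2, SD 0.1995, against 0.0365 in knockout). A shift of all genes within that spread would not show. By the authors' deposited values 1262 genes were higher and 793 lower at an adjusted p under 0.05, and 1033 of the 1049 genes were called in both with the same direction.

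The number of calls depended on single libraries and on how replicates 1 and 2 were counted. Without WT replicate 1 the total was 555, without WT replicate 2 530 and without knockout replicate 3 2603, against 1049, and the counts of at least 2-fold changes were 534, 431 and 1286 against 839. With replicates 1 and 2 alone, a fit that treats their small spread as known, 1006 genes rose and 1062 fell. With replicates 1 and 2 averaged 150 rose and 25 fell, all of them among the 1049. Median-of-ratios scaling gave 839 higher and 625 lower genes, so that 57.3% of calls were higher instead of 70.6%, and TMM scaling 830 and 612 (57.6%). Scaling to equal totals gave 834 and 523 (61.5%), and on recovered reads edgeR called 878 higher and 533 lower with TMM.

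Immunoglobulin genes moved in both directions. Of the 12 tested members of the list of constant regions and light chain parts, Ighg2b, Ighg2c and Ighg3 rose, Jchain and Iglc1 fell and 7 did not pass (3 up and 6 down adjusted over the list alone). Ighg2b (chromosome 12, 113302965 to 113307933) went from 63.7 ± 16.3 to 1045 ± 192 (16.3-fold, adjusted p = 3.2e-07), Ighg2c rose 6.97-fold (adjusted p = 1.0e-03), and Ighg3 went from 850 ± 333 to 2197 ± 68.3. Ighm, the constant region of the IgM that these cells express, was at 192936 ± 36179 in WT and 142423 ± 2214 in knockout (log2 fold change -0.42, SE 0.18, adjusted p = 0.236). Every knockout value of Ighm lay below every WT value, although it did not pass. The list as a set did not pass camera (adjusted p = 0.135), but did, downward, with a term for replicate 3 (0.0432), an alternative chosen after the data were seen. Ighg2b and Ighg2c are near-identical in parts, as are the lambda constant genes, so reads may have been split between them.

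Plasma cell genes were lower as a set by camera with the preset correlation, but not with an estimated one. Of 16 tested members 4 fell and none rose. Jchain, the transcription factor gene Zbtb20 (9294 ± 2316 to 3451 ± 1177, adjusted p = 4.0e-03), Cd28 and Fkbp11 fell, and adjusted over the list alone 6 fell and 1 rose. The regulators Prdm1, Irf4 and Xbp1 had log2 fold changes of -0.26, -0.34 and -0.44, with adjusted p of 0.791, 0.433 and 0.24. Camera gave an adjusted p = 1.7e-06 with the preset correlation, and the adjusted p was 0.691 with an estimated correlation. Without WT replicate 2 the adjusted p of Zbtb20 was 0.0947.

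Genes of B cell identity and receptor signalling did not pass as a set, with calls in both directions. Of 31 tested members 5 fell, namely Cd37, Bank1, Ms4a1 (which encodes CD20), Ebf1 and Cd22, and the kinase gene Syk rose (adjusted over the list alone, 7 fell and 2 rose). Cd37 went from 4620 ± 565 to 2367 ± 104 (1.94-fold lower, adjusted p = 3.5e-03), Bank1 from 3168 ± 408 to 1602 ± 133, and Syk from 13020 ± 1705 to 22522 ± 1878. Pax5, the master regulator of the lineage, had a log2 fold change of -0.0058 (adjusted p = 0.998). The set did not pass (camera adjusted p = 0.112), although it did, downward, without WT replicate 1 (0.0419) or without a filter (0.045), and Syk lost its call without that library (adjusted p = 0.108).

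In the germinal centre list Cxcr4 and Mef2c fell and Basp1 rose among 17 tested members (6 down and 4 up adjusted over the list alone, camera adjusted p = 0.754). Cxcr4, the receptor for the chemokine CXCL12, went from 3152 ± 561 to 1162 ± 395 (adjusted p = 1.9e-03), and Mef2c from 19011 ± 5517 to 9296 ± 1457. The list's median was 0.05 and its mean 0.02 where camera pointed down. Without WT replicate 2 the adjusted p was 0.0878 for Cxcr4 and 0.121 for Mef2c. Without WT replicate 1 it was 0.11 for Mef2c and 0.0985 for Basp1, which was at 0.0522 without WT replicate 3.

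Genes for antibody gene mutation and class switching had few calls in limma. Of 34 tested factors of these processes, the ligase gene Lig4 fell (538 ± 86.2 to 279 ± 39.1, adjusted p = 0.019) and 33 did not pass (camera adjusted p = 0.118, and 0.0456, downward, without a filter). Lig4 lost its call without WT replicate 1 (0.0562), 2 (0.106) or 3 (0.0504). Of 25 tested genes known as targets of the mutation process Btg1 rose 2.64-fold and Cxcr4 fell 2.78-fold (camera adjusted p = 0.818), Btg1 with an adjusted p of 0.0578 without WT replicate 2. Adjusted over the list alone, the calls numbered 0 up and 1 down among the factors and 1 up and 1 down among the targets. At an unadjusted p under 0.05 in limma were 4 of the factors and 7 of the targets, against 2585 of all 15794 genes. Among the factors edgeR called 2 with TMM and 1 with the authors' size factors, and DESeq2 4. Among the targets these numbers were 3, 2 and 6.

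None of the 38 tested genes for polymerase pausing and elongation factors passed in limma, with 3 at an unadjusted p under 0.05. Polr2a, the largest polymerase subunit, was at 20122 ± 5235 in WT and 21270 ± 3766 in knockout, and Ssrp1 at 23160 ± 4789 and 21383 ± 2773. Aff1, a subunit of the super elongation complex, had a log2 fold change of -0.65 (adjusted p = 0.0542, and 9.4e-03 with the replicate block). edgeR called 2 of these genes with TMM and 0 with the authors' size factors, DESeq2 4, and the set did not pass (camera adjusted p = 0.433). Among the 7 DOT1L partners Dot1l alone passed (1 up and 1 down adjusted over the list alone, camera adjusted p = 0.194), and Mllt6 had a log2 fold change of 0.60 (adjusted p = 0.0788, and 0.02 with the block).

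Chromatin regulators and developmental targets of Polycomb had few calls. The set of 20 Polycomb members did not pass (camera adjusted p = 0.508). In the PRC2 target list Gata6 rose, from 11.5 ± 1.78 to 55.7 ± 18.3, and Lhx2 fell, from 93.3 ± 19.3 to 27.0 ± 7.44, with 15 of 17 members not passing. None of 30 histone methyltransferases and demethylases passed in limma (3 at an unadjusted p under 0.05, 1 called by edgeR with TMM, 0 with the authors' size factors and 4 by DESeq2). Nsd2 had a log2 fold change of -0.40 (adjusted p = 0.29) and passed under the 3 other scalings (0.0253, 0.0237 and 0.024). The camera adjusted p of these 2 lists was 0.698 and 0.243, and adjusted over the list alone they held 2 and 0 calls. Lhx2 had an adjusted p of 0.0628 without WT replicate 2.

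Interferon-stimulated genes rose as a set by camera with the preset correlation, but not with an estimated one. Of 26 tested members 10 rose and none fell: Usp18, Oas1a, Igtp, Bst2, Oasl2, Ifih1, Oas3, Irf7, Xaf1 and Gbp2 (12 up and 1 down adjusted over the list alone). Usp18, a protease that removes the ubiquitin-like modifier ISG15, rose 6.99-fold (42.6 ± 5.80 to 322 ± 146, adjusted p = 7.1e-05), and Oas1a rose 5.37-fold (29.6 ± 9.34 to 159 ± 6.17). Camera gave an adjusted p = 7.7e-06, and the adjusted p was 0.691 with an estimated correlation. Nlrc5, the transactivator of MHC class I genes, fell 2.98-fold (4536 ± 725 to 1547 ± 439, adjusted p = 4.0e-04), while the other 20 antigen presentation genes did not pass (camera adjusted p = 0.818; 0 up and 1 down adjusted over the list alone).

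In the NF-kB list Tnfaip2, Nfkbia and Lta rose and 21 of 24 members did not pass (3 up and 0 down adjusted over the list alone, camera adjusted p = 0.159). Nfkbia, the inhibitor of the pathway, went from 8220 ± 1143 to 15091 ± 3574. Its adjusted p was 0.159 without WT replicate 1 and 0.09 without WT replicate 2, and that of Tnfaip2 0.145 without WT replicate 1 and 0.0603 without WT replicate 3.

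Of 17 p53 target genes Phlda3, Cdkn1a and Pmaip1 rose and Plk2 fell (3 up and 1 down adjusted over the list alone, camera adjusted p = 0.298). Phlda3 rose 5.997-fold, from 34.7 ± 4.06 to 214 ± 31.3, and the cell cycle inhibitor gene Cdkn1a 2.72-fold, from 597 ± 133 to 1614 ± 317. Cdkn1a and the cyclin gene Ccnd2 (2.64-fold) rose among 12 cell cycle inhibitors and D cyclins (2 up and 2 down adjusted over the list alone, camera adjusted p = 0.159), with adjusted p of 0.0532 and 0.0556 without WT replicate 2. None of 32 cell cycle and replication genes passed in limma (1 at an unadjusted p under 0.05, 1 called by edgeR with TMM, 0 with the authors' size factors, 2 by DESeq2, camera adjusted p = 0.706). Mki67 was at 27554 ± 4823 in WT and 25800 ± 3162 in knockout, and Top2a at 31216 ± 5929 and 38349 ± 227. The list median was lower in replicate 3 than in replicates 1 and 2, by -0.29 in WT and -0.61 in knockout (log2, median-of-ratios scaling). None of 22 apoptosis regulators passed in limma (7 at an unadjusted p under 0.05, 3 called by edgeR with TMM, 0 with the authors' size factors, 5 by DESeq2, camera adjusted p = 0.765), with Mcl1 at 18752 ± 2557 and 22711 ± 5848.

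The stress response list was lower as a set by camera with the preset correlation, but not with an estimated one. Atf5 and Trib3 fell and 18 of 20 members did not pass (0 up and 3 down adjusted over the list alone). Atf5, a transcription factor of the integrated stress response, went from 6459 ± 1164 to 3116 ± 468 (adjusted p = 3.9e-03), and Trib3 from 4508 ± 662 to 2583 ± 194. Camera gave an adjusted p = 3.9e-04, and the adjusted p was 0.988 with an estimated correlation and 0.162 without knockout replicate 3. Without WT replicate 2 the adjusted p was 0.0711 for Atf5 and 0.0612 for Trib3.

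Glycolysis and sterol synthesis genes were higher as sets by camera with the preset correlation, but not with an estimated one (adjusted p 0.997 for both), with few or no single calls. Pfkl (4297 ± 961 to 7335 ± 378) and Tpi1 (14597 ± 3308 to 24033 ± 1794) rose among 18 glycolysis genes (2 up and 0 down adjusted over the list alone). The set's adjusted p was 0.0231, or 0.136 with the replicate block, and 0.138, 0.0539 and 0.374 without WT replicate 3, knockout replicate 1 or knockout replicate 3. Pfkl and Tpi1 had adjusted p of 0.156 and 0.179 without WT replicate 1, and of 0.105 and 0.17 without WT replicate 3.

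None of 23 sterol genes passed in limma (1 at an unadjusted p under 0.05, 0 called by edgeR with either scaling, 1 by DESeq2), against 8 with the block, among them Cyp51 (9163 ± 3573 and 14779 ± 5520, adjusted p = 0.468, and 4.2e-03 with the block). The sterol set had an adjusted p of 0.0152, and of 0.499, 0.329 and 0.366 without WT replicate 3, knockout replicate 1 or knockout replicate 2. The replicate 3 libraries were low in sterol genes in both genotypes (list medians of -0.81 in WT and -1.49 in knockout against replicates 1 and 2, log2, median-of-ratios scaling).

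Housekeeping lists showed no calls in limma. None of 24 MYC target genes of the ribosome and nucleolus (2 at an unadjusted p under 0.05), 31 cytosolic ribosomal protein genes (0) and 25 oxidative phosphorylation genes (0) passed, and edgeR and DESeq2 called 0 in each. Npm1 was at 235315 ± 37120 in WT and 241912 ± 9428 in knockout, Rpl4 at 140287 ± 16759 and 131904 ± 11854, and Atp5b at 67903 ± 10072 and 66951 ± 5067. The camera adjusted p was 0.496, 0.855 and 0.985. Without knockout replicate 1 or 2 the MYC target set passed, at 0.0232 and 0.0345. In replicate 3 the median of this list was at -0.37 in WT and -0.89 in knockout against replicates 1 and 2 (log2, median-of-ratios scaling).

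Adhesion and trafficking receptors moved in both directions, with 4 rising (Itgam, Itgax, Cd9 and Ccr6) and 3 falling (Gpr183, Cxcr4 and S1pr3) among 21 tested (6 up and 3 down adjusted over the list alone, camera adjusted p = 0.159). The integrin gene Itgax rose 16.5-fold, from 4.58 ± 3.46 to 81.4 ± 39.4, and Gpr183, a receptor that guides B cells within follicles, fell 4.497-fold, from 280 ± 48.3 to 66.2 ± 32.8. Gpr183 had an adjusted p of 0.0881 without WT replicate 2.

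Some markers of other cell types were higher in knockout, and 5 of their lists passed camera with the preset correlation but none with an estimated one (adjusted p 0.691 or 0.997). Of 7 tested fibroblast and stromal markers Vim, Pdgfrb, Pecam1 and Sparc rose, of 9 erythroid and megakaryocyte markers Hba-a1, Hba-a2, Gp9 and Epor rose, and of 10 myeloid markers Lyz2, Itgam and Tyrobp rose and Mrc1 fell. Cd4 rose among 13 T cell markers, Cd93 among 5 early progenitor markers and Il2rb (3.78-fold, adjusted p = 9.8e-05) among 2 tested markers of NK cells, too few for a set test. Cd7 was at 727 ± 377 in WT and 4194, 3730 and 57235 in the knockout libraries (limma adjusted p = 0.197). Without knockout replicate 3 its log2 fold change was 2.56 (limma adjusted p = 1.7e-32). The knockout spread in that fit is only that between the nearly alike replicates 1 and 2, so the p-value overstates the evidence. Hba-a1, which is a close copy of Hba-a2, rose 2.79-fold. The best expressed myeloid and progenitor markers were Ctss (11824 ± 1616 and 10920 ± 1102) and Flt3 (704 ± 109 and 917 ± 109), which did not pass.

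With the preset correlation these 5 sets had adjusted p of 1.8e-05 (fibroblast), 1.4e-03 (erythroid), 0.0288 (myeloid), 0.0107 (T cell) and 0.0107 (progenitor). With an estimated correlation the adjusted p was 0.691 for 4 of them and 0.997 for the myeloid set. The T cell and myeloid sets lost their calls under median-of-ratios scaling (0.0522 and 0.0804), TMM scaling and equal totals, and without WT replicate 2 (0.135 and 0.283). The myeloid set also did so without knockout replicate 3 (0.157), and the progenitor set without WT replicate 2 (0.108). Adjusted over the list alone, 4 fibroblast, 4 erythroid, 4 myeloid, 1 T cell, 2 progenitor and 2 NK markers rose and 2 myeloid markers fell.

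**Figure D3:**
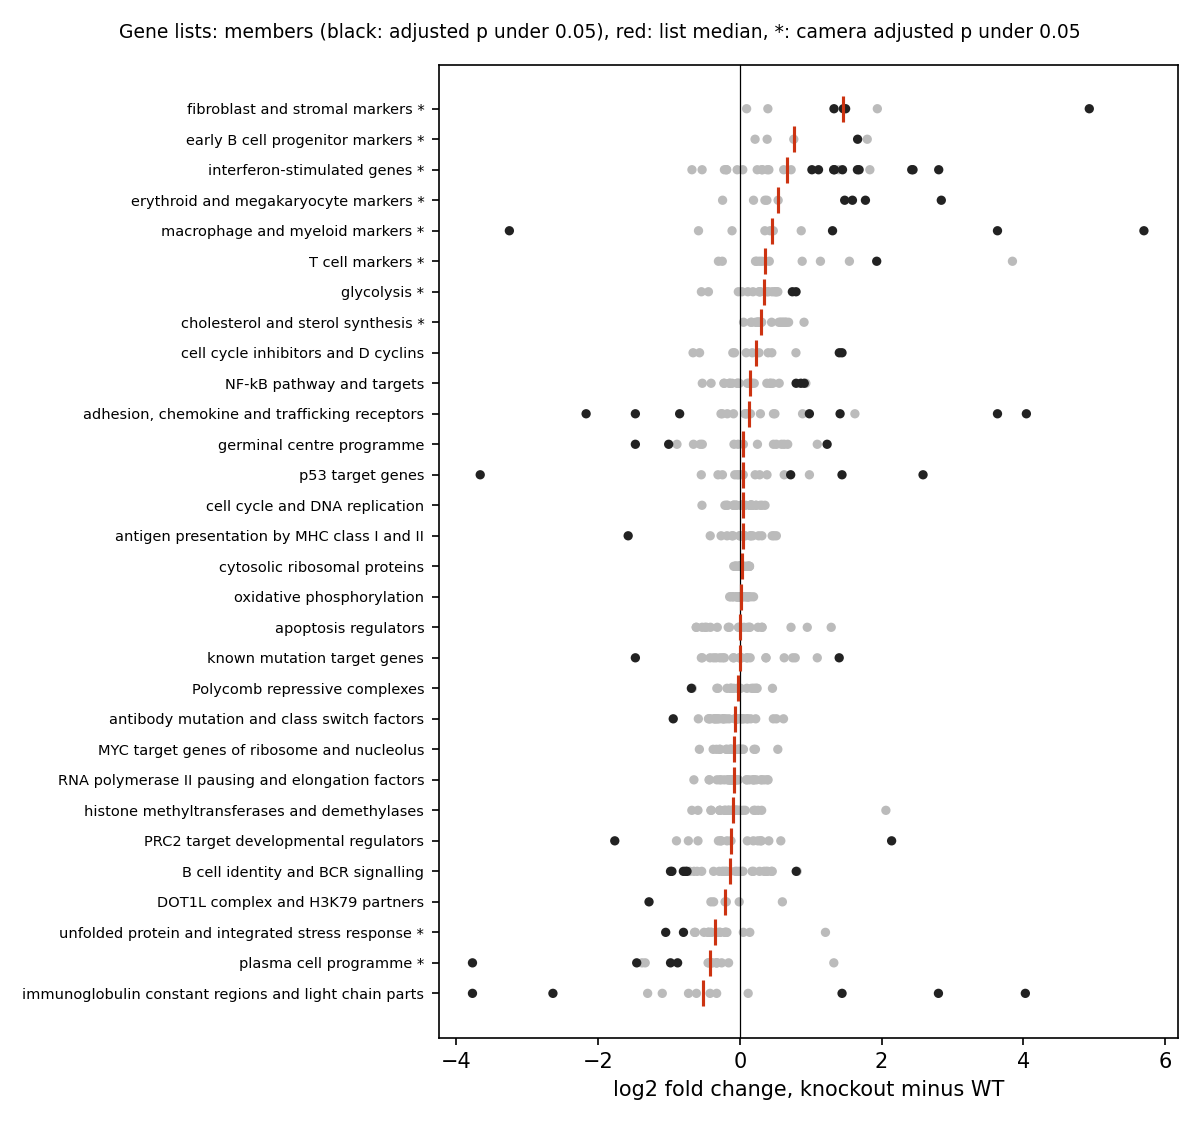
Log2 fold changes (x axis) of the members of the 30 tested gene lists, 1 row per list, with members past an adjusted p of 0.05 in black, others in grey, the list median as a red bar, and an asterisk at lists past camera with the preset correlation. The 10 marked lists are 8 shifted upward and 2 shifted downward, the plasma cell and stress response lists.

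Of 30 lists tested 8 passed upward and 2 downward with the preset correlation, and 7 and 2 with the replicate block. At least as many passed with the preset correlation in 5 of the 10 splits of the libraries into 3 and 3, the real one included. Another split gave 14, so the number of passing lists does not set the genotype apart. None passed with an estimated correlation (lowest adjusted p 0.691, 1 list at an unadjusted p under 0.05) or by fry, which tests whether the members of a list move one way (lowest adjusted p 0.0909, 7 lists at an unadjusted p under 0.05). The mixed test of fry asks whether members change in either direction, and some lists passed it. Its adjusted p was 5.7e-05 for PRC2 targets, 2.3e-04 for the immunoglobulin list and 2.6e-03 for mutation targets, but 0.669 for the cell cycle list. That test does not compare a list with other genes, so a pass does not set a list apart.

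With the replicate number as a block more list members passed in limma. The immunoglobulin list then held 3 rising and 6 falling genes, B cell identity 2 and 9, plasma cell genes 1 and 6, the germinal centre list 2 and 6, mutation targets 3 and 3, and mutation and class switch factors 0 and 2. Histone methyltransferases and demethylases held 1 and 2, apoptosis regulators 2 and 3, MYC targets 1 and 1, and cell cycle inhibitors 3 and 2. Glycolysis held 3 and 1, NF-kB 5 and 1, the stress response 0 and 4, and PRC2 targets 1 and 2. Interferon genes held 14 and 1, trafficking receptors 6 and 3, p53 targets 4 and 1, myeloid markers 4 and 1, and fibroblast markers 5 and 0. T cell, progenitor and NK markers then rose in 3, 3 and 2 cases, and DOT1L partners held 1 and 1.

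The longest genes were lower by median and camera and the shortest higher, although among the longest more genes were called higher (91) than lower (69). The 1191 longest protein-coding genes by span (104.8 kb or more) had a median log2 fold change of -0.15 and a mean of 0.05, which differ in sign, and the 1191 shortest (up to 4.52 kb) a median of 0.08 and a mean of 0.15. Both sets passed camera (adjusted p = 0.0122), but not with the replicate block (0.171 and 0.145) or with an estimated correlation (adjusted p = 0.71). Across 11904 protein-coding genes, which are not independent replicates, the rank correlation (Spearman) of fold change with span was -0.205. The calls were also lost without WT replicate 3 (0.109 and 0.0668), knockout replicate 1 (0.676 and 0.45) and knockout replicate 2 (0.319 and 0.195).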

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

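The replicate 3 term, replicates 1 and 2 alone, replicates 1 and 2 averaged and median-of-ratios scaling with the replicate block were chosen after the data were seen. Of 54 named called genes 33 kept their call without each single library, and 21 lost it without some WT library (16 without WT replicate 2). With replicates 1 and 2 averaged 29 lost it, 0 lost it by another scaling and Tpi1 alone lost it with replicates 1 and 2 only. Across 1530 alternative values of named genes 1421 kept direction and side of the threshold, 61 fell below it and 13 rose above it, and across 598 of lists 521, 42 and 6 did. The replicate block ended no call of a named gene. A scaling to the fly spike-in was not run, since no fly genes were used here. Genes near the filter are limited by depth, and in simulated counts most 1.5-fold changes were missed.

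The 1049 changed genes became 1703 without a filter, 1989 with the replicate block, 2506 with DESeq2, 2378 with a term for replicate 3, 2068 with replicates 1 and 2 only, 175 with replicates 1 and 2 averaged, 2331 with median-of-ratios scaling and the block, 593 at an adjusted p under 0.01 and 2055 by the authors' deposited adjusted p-values. They ranged from 530 to 2603 with single libraries left out. The 839 changed at least 2-fold became 1293 without a filter, 550 with a filter at 50, 1265 with replicates 1 and 2 only and 175 with these averaged, and ranged from 431 to 1286 with single libraries left out. The cause was not tested. Dot1l had a log2 fold change of -1.1967 with replicates 1 and 2 averaged (adjusted p = 0.0888) and kept its call under the other alternatives. The 10 lists became 0 with an estimated correlation and 0 by the test of fry for movement one way, and ranged from 7 to 11 with single libraries left out.

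For the longest genes the adjusted p of 0.0122 became 0.1456 without a filter, 0.171 with the block, 0.1472 with the replicate 3 term and 0.7099 with an estimated correlation, and ranged from 0.0009294 to 0.6756 with single libraries left out. For the shortest genes it became 0.06318, 0.1454, 0.1309 and 0.7099, and ranged from 0.002698 to 0.45. The cause was not tested.

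Log2 fold changes of 12 named genes changed sign, past the threshold in neither fit, and the cause was not tested. Kdm2b was at -0.0018 with median-of-ratios and -0.0002 with TMM scaling and at -0.0604 with replicates 1 and 2 averaged. With replicates 1 and 2 only, Birc3 was at -0.1589, Npm1 at -0.0198, Ncl at 0.0211 and Srebf2 at -0.0243. Ncl was at 0.0126 with equal totals, 0.0422 by edgeR with TMM and 0.0141 by DESeq2, and Atp5b at 0.0128 by edgeR with TMM.

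With single libraries left out, log2 fold changes that changed sign ranged from -0.2143 to 0.0579 for Ssrp1, -0.0866 to 0.2883 for Polr2a, -0.1222 to 0.2588 for Kdm2b, -0.1765 to 0.0513 for Mki67, -0.1207 to 0.1204 for Birc3, -0.0308 to 0.1758 for Npm1, -0.1751 to 0.1959 for Ncl, -0.1704 to 0.0017 for Rpl4, -0.1416 to 0.0433 for Rpsa, -0.0807 to 0.1057 for Atp5b, -0.0299 to 0.1606 for Atp5a1 and -0.1313 to 0.2538 for Srebf2.

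Of the lists, 8 changed direction under some alternative, past the threshold in neither fit, and the cause was not tested. Their adjusted p was 0.9549 by fry for the germinal centre list and 0.5467 without a filter for PRC2 targets. It was 0.6486 with replicates 1 and 2 only for MYC targets. For ribosomal proteins it was 0.9915 without a filter, 0.902 with the block, 0.9222 with the replicate 3 term and 0.8961 with replicates 1 and 2 only. For oxidative phosphorylation it was 0.9467 without a filter, 0.902 with the block, 0.9078 with the replicate 3 term and 0.7604 with replicates 1 and 2 averaged. For antigen presentation it was 0.8792 with the block, 0.8917 with the replicate 3 term and 0.4546 with replicates 1 and 2 only. The ranges with single libraries left out cover all such fits, also those that kept their direction. They were 0.3967 to 0.9524 for mutation targets, 0.09196 to 0.6208 for the cell cycle and 0.02324 to 0.8559 for MYC targets. For ribosomal proteins the range was 0.2041 to 0.9403, for oxidative phosphorylation 0.2834 to 0.9524 and for antigen presentation 0.252 to 0.9333. The 0.02324 of MYC targets, without knockout replicate 1, is past the threshold and kept the downward direction of the main fit.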

Other observations

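The tests of library scaling, read depth and slower growth in replicate 3, of cells of other types, and both tests of related neighbours were chosen after the result was seen, as were the genes named in this part outside the naming rule. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many changed genes, 1049 against a highest other of 0, and 1 gave as many genes changed at least 2-fold, 839 against 0. For lists past camera, 5 of the 10 splits gave as many, 10 against a highest other of 14 (11 among the other splits that part all 3 pairs). For the longest genes, 5 of the 10 gave as small a camera p, 9.4e-03 against a lowest other of 1.5e-09 (8.2e-09 among those that part all 3 pairs). The splits are too few for a share under 0.05.

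Among genes picked for it, Sqle and Rrm2 were low in replicate 3 of both genotypes, while Txnip, Fas and Trp53inp1 were high. Sqle was at 6857, 8846 and 4199 in WT and 10988, 10825 and 3603 in knockout replicates 1 to 3, and Rrm2 at 5868, 7542 and 4032 in WT and 8540, 8051 and 2703 in knockout. Txnip was at 4619, 6001 and 11964 in WT and 7365, 6966 and 27441 in knockout, and Fas at 232, 269 and 471 in WT and 275, 257 and 1531 in knockout. Pdcd1 and Lag3 were high in knockout replicate 3, at 2166 and 3181, against 511 and 659 in knockout replicate 1.

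Library scaling as the whole of the replicate 3 difference is argued against, since a factor moves all genes of a library alike and adds no spread across genes, whereas the SD across genes of replicate 3 against replicates 1 and 2 was 2.58 times that of replicate 1 against 2 in WT (5.29 times in knockout). Read depth is argued against as well, since 2 of 2 replicate 3 libraries had a read total within the range of the other 4. A slower-growing culture in replicate 3 remains open as a hypothesis, since cell cycle, MYC target and sterol lists were all lower in it, with the highest of the 6 medians at -0.2924. A growth count of the cultures was not analysed here.

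In the knockout cultures stromal cells are argued against as the source of Vim, and T cells as that of Cd4 and Cd7. Transcripts abundant in such cells gained little beside them. Macrophages or granulocytes as the source of Tyrobp are argued against by Lyz2 alone. The gain of Col1a1, Col1a2, Col3a1 and Sparc reached at most 2.35% of that of Vim in any pair, and the gain of Lyz2 at most 5.47% of that of Tyrobp. Csf1r, also on the myeloid list, did gain without passing, from a mean of 1396 in WT to 1932 in knockout, against 956 and 2350 for Tyrobp. The gain of Cd3 and T cell receptor constant genes reached 3.97% of that of Cd4 and 0.744% of that of Cd7. For Itgam and Lyz2, myeloid cells and expression by the knockout cells cannot be told apart, since the gain of Lyz2 was 82%, 119% and 33.9% of that of Itgam in the 3 pairs, although Cd14 and S100a8 were at 0 in all 6 libraries. Expression by the knockout B cells may account for these genes, a hypothesis found on the same data, while NK and innate lymphoid cells (for Cd7 and Tyrobp), erythroid cells and other stromal markers were not tested.

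Mature transcript length went with at least part of the trend of fold change with span. The rank correlation was -0.178 with exonic length, and that with span went from -0.205 to -0.118 given exonic length. That remainder cannot decide whether mature length is the whole of the trend. Exonic length merged all annotated exons of a gene, and so only approximates the transcripts present in these cells. Expression level as the whole of the trend is argued against by -0.173 given the mean. Drift between cultures and an effect of the genotype cannot be told apart. Span correlated at 0.189 with replicate 3 minus replicates 1 and 2 in knockout and 0.06 in WT, and with replicate 1 minus 2 at -0.209 and -0.11. The 3 pairs gave -0.261, -0.247 and -0.018, so the third barely showed the trend.

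A further hypothesis was that genes next to each other rose together. Next to each other means consecutive among the tested genes counted, with all other genes skipped and no limit on distance. Some pairs lay far apart, such as Armcx2, ending at 134809221, and Nxf7, starting at 135579555 on chromosome X. Examples were Phlda3, Tnni1 and Lad1, Gpr162 and Cd4, and Tfpi and Ctnnd1. Adjacent pairs with both genes higher numbered 110, against a mean of 34.68 in random placings of the calls, and 71 against 31.49 without pairs that share a symbol stem or first 3 letters (one-sided permutation p = 1e-04, the smallest possible). Related, overlapping or weakly expressed neighbours as the whole of it, as far as symbols show kinship, are argued against by 58 pairs against 30.36 (one-sided permutation p = 1e-04) among non-overlapping protein-coding genes matched for level. With predicted genes dropped, and pairs sharing 2 letters or 1 of 4 families left out (related neighbours whose symbols differ), 50 remained against 30.58 (highest random count 52, one-sided permutation p = 4e-04). Other kinships were not removed, and the distance between neighbours was not taken into account. The random placings treat genes as independent, so their p-values do not measure the spread between libraries. Neighbouring genes that fell, or that differed between libraries of 1 genotype, were not counted for comparison. Spread of transcription over close neighbours may underlie some of the pairs but was not tested.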
